A study of Mus musculus and Arabidopsis thaliana with 87 samples.

How the data were processed

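The series concerns intrinsically disordered regions of demethylases and where on the genome these enzymes act. Mouse E14TG2a embryonic stem cells (WT, Alkbh5 KO and Alkbh5 del-cIDR, or cells expressing KDM4A, KDM4B, KDM6A or KDM6B in full length or without a disordered region) and Arabidopsis seedlings were assayed by nascent RNA sequencing, chromatin-associated RNA sequencing with and without m6A enrichment, eCLIP and chromatin profiling. Of the 87 samples, 65 are mouse and 22 Arabidopsis, and each is the only sample of its group. Groups were taken from the sample labels. The tables name the del-cIDR line by a knock-in code, and their libraries were matched to the labels by genotype and labelling time.

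The nascent gene table holds counts of reads per gene that the authors made with featureCounts 2.0.3 per the file headers, on Ensembl release 110 annotation of GRCm39 with a Drosophila spike-in sequence, with a minimum mapping quality of 30. Counting was not strand-specific, and reads with several placements were left out by the tool's default, so reads of overlapping genes on opposite strands cannot be separated and near-identical genes lose reads. The nascent repeat table was made in the same way, per repeat copy, and the KDM repeat table from unfiltered alignments with no mapping quality minimum given. Repeat copies carry only class and family, so the planned subfamilies were replaced by 60 families. The deposited peak lists give a fold enrichment over the control (a ratio) and -log10 q, both from the authors' peak caller, in the format of MACS2. Their other columns are deposited start, end and summit positions in bp, as are the Arabidopsis region lists, which have no score. The submitters' processing notes name fastp, HISAT2, STAR, BWA, UMI-tools, SAMtools, Picard, MACS2 and featureCounts and the builds GRCm39 and TAIR10, and their versions other than that of featureCounts are not given in the sources used here.

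Gene symbols were matched by Ensembl identifier for 51948 of 56941 genes (91.2%). The nascent test was edgeR 4.0.16 quasi-likelihood on counts scaled by TMM and filtered with filterByExpr, with genotype and labelling time as factors and 6 residual degrees of freedom. For KDM repeats the factors were protein and presence of the disordered region, with 3 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The interaction test used genotype by log2 minutes. Nascent repeat counts were scaled with the factors of the gene table. DESeq2 1.42.0 served as the second tool. Gene lists were tested with camera (preset and estimated correlation) and fry in limma 3.58.1, over 28 mouse lists. These are pluripotency, primed pluripotency, 2-cell-like, trophoblast, primitive endoderm, mesoderm, neural ectoderm, fibroblast, Hox and Polycomb targets, germline, imprinted, m6A machinery, histone lysine demethylases, H3K9 methylation, Polycomb complexes, enhancer cofactors, p53 targets, interferon response, amino acid and ER stress response, heat shock, immediate early, cell cycle, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded, nuclear noncoding RNA, ribosomal proteins and replication-dependent histones. The fry test asks whether the genes of a list move one way on balance and does not compare them with other genes. Its adjusted p for 2-cell-like genes was 0.00159 in KO and 0.000128 in del-cIDR.

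Peaks were assigned by summit to exons, introns or intergenic sequence and to repeat copies, and overlaps of at least 1 bp counted as shared (bedtools 2.31.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6). Random placements of eCLIP peaks within the genes that hold them were drawn 1000 times. Genes along chromosomes were summarised in windows of 10 Mb with at least 10 genes of mean count 50 or more, and a window is called shifted when its median log2 ratio lies beyond 0.2 on the same side at all 4 times. Copies of 5 kb or longer were treated as long. R 4.3.3, its package data.table (version 1.17.8) and matplotlib 3.10.9 were used as well.

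The groups, the tests, the gene lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names Alkbh5, the 10 largest rises and 10 largest falls among called genes with a mean count of at least 50 and the same direction at every time, up to 4 members per list, and the 6 strongest peaks per class, from which examples are given, without unnamed gene models. A few genes that the rule picks are not reported here. Nlrp4a and Nlrp9c are set beside the repeat copies next to them, and the members Pramel7 and Eif1a are named, because of their values. Values of single libraries use CPM (counts scaled to library size) with a prior count of 2, and genes needed 200 counts over the pair. Their 95% intervals cover counting error only, not the spread between cultures.

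On simulated data with 200 genes changed, the nascent test called 71.6% of 1.5-fold and 98.5% of 2-fold changes in the KO contrast with 16 false calls, and 70.1% and 98.5% in the del-cIDR contrast with 11. The repeat family test called 10 of 10 families changed 2-fold in both tables, drawn from families with many reads. The interaction test called 87.5% of genes changed 2-fold per doubling of labelling time. Smaller changes of families or with time were not simulated, so these tests may miss them. No unchanged list was called by camera and 1 was called by fry. The simulated genes were drawn independently of each other. This therefore does not show how often unchanged lists of correlated genes are called. Alternatives covered scaling, filtering, the second tool, leaving out each time or protein, peak thresholds and the definition of overlap. The comparison of KO with del-cIDR, spike-in scaling, leaving out the del-cIDR 10 min library, the calls outside shifted windows, the division of repeats by place and length, the single copies and the KDM4 and KDM6 pairs were added after the data had been seen.

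Chromatin libraries (ATAC, CUT&Tag, CUT&RUN), genes in the KDM cells, and m6A enrichment per gene were not analysed here. The 16 other columns of values per sample in the KDM repeat table were not used here. The Arabidopsis lists other than Col-0 carry codes that the labels do not explain, so they form no comparison.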

Results

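The series holds 87 samples, 65 from mouse embryonic stem cells and 22 from 10-day Arabidopsis seedlings, each numbered replicate 3 and alone in its group. The comparisons rest on 12 nascent RNA libraries (WT, Alkbh5 KO and Alkbh5 del-cIDR cells labelled with ethynyl uridine for 10, 20, 40 and 60 min), 8 chromatin-associated RNA libraries of cells expressing KDM4A, KDM4B, KDM6A or KDM6B in full length (FL) or without an intrinsically disordered region (del-IDR), and the authors' peak or region lists for m6A, ALKBH5 eCLIP and Arabidopsis RNA. Nascent libraries held 3918731 (del-cIDR, 10 min) to 19513922 (WT, 60 min) reads in genes, and the KDM libraries 26084574 (KDM4A del-IDR) to 45930644 (KDM6A FL) reads in repeats. With 1 sample per group, the 4 labelling times or the 4 proteins serve as the only repeats. The p-values therefore measure how far a difference varies between times or between proteins. They do not measure the spread between repeated cultures of 1 group, and technical and biological scatter cannot be separated.

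Chromatin-associated m6A differed between the genotypes mainly in how many peaks lay on L1 retrotransposons. The Alkbh5 KO list was longer than the WT list and the del-cIDR list shorter, and in both cases L1 copies made up most of the difference. Peaks in exons were close in number in the 3 lists. No test was possible, since there is 1 list per genotype, and whether a list pools libraries is not stated.

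WT cells had 43142 m6A peaks covering 19.5 Mb, KO cells 52765 covering 24.8 Mb and del-cIDR cells 31110 covering 13.9 Mb. An L1 copy lay at the summit of 16413 peaks in WT (38.0%), 27267 in KO (51.7%) and 8029 in del-cIDR (25.8%). Copies of 5 kb or longer carried 80.4%, 80.2% and 81.6% of these, which is the size range of full-length L1. The L1 peaks were split between intergenic copies (10811 in WT, 18347 in KO, 5264 in del-cIDR) and copies in introns (5435, 8729 and 2660). Exonic summits numbered 15714, 15284 and 14026. Endogenous retroviruses moved much less, with 1315, 1149 and 1215 ERVK peaks and 1761, 1950 and 1666 ERVL peaks in WT, KO and del-cIDR.

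**Figure D1:**
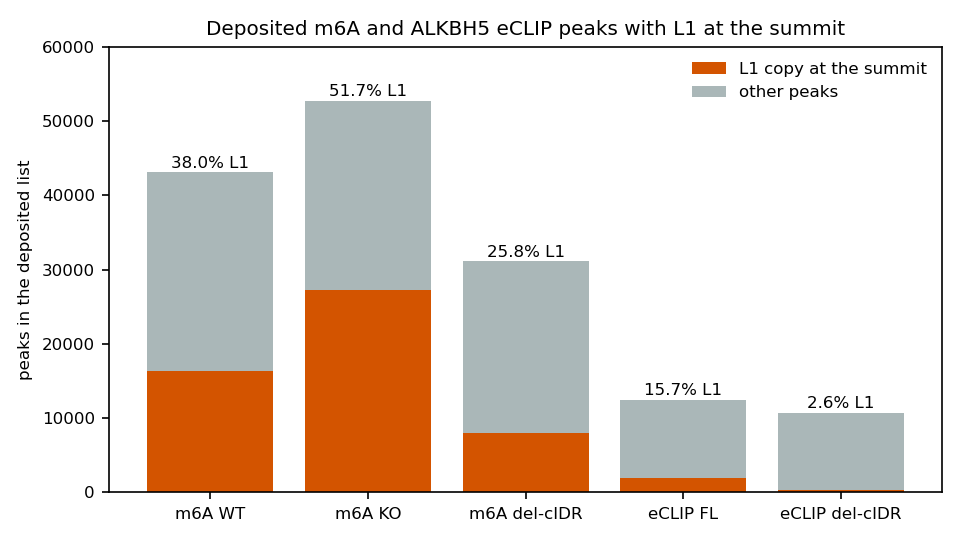
Number of peaks in each deposited list (bars, 1 list per genotype) divided into peaks with an L1 copy at the summit (orange) and other peaks (grey). L1 takes 51.7% of the KO m6A list, 38.0% of the WT list and 25.8% of the del-cIDR list, and 15.7% and 2.56% of the FL and del-cIDR eCLIP lists.

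Of the WT peaks, 84.0% overlapped a KO peak and 63.7% a del-cIDR peak, while 91.2% of del-cIDR peaks overlapped a WT peak. The 17641 KO peaks without a WT partner had an L1 copy at the summit in 13398 cases (76.0%), and the 15674 WT peaks without a del-cIDR partner in 9809 cases (62.6%). At the level of genes the lists were closer, with 13223 genes holding a peak in WT, 13039 in KO (11990 shared with WT) and 11857 in del-cIDR (11425 shared). Among the strongest peaks of the WT list found in all 3 genotypes were an intronic peak of Samd4b (chromosome 7, 28185451 to 28185774, fold 248) and an exonic peak of Kalrn (chromosome 16, 33792804 to 33793024, fold 246). KO peaks absent from WT included Ninj2 (chromosome 6, 120136009 to 120136235, intron, fold 48.8) and an L1 copy in an intron of the histone deacetylase gene Hdac9 (chromosome 12, 34117989 to 34118524). WT peaks absent from del-cIDR included Mid1 (X chromosome, 168778294 to 168778951, intron, fold 133), an L1 copy in an intron of the kinase gene Camk4 (chromosome 18, 33165288 to 33165561, fold 21.7) and an exon of Nfam1 (chromosome 15, 82883290 to 82883671, fold 19.2). The strongest named del-cIDR peak absent from WT lay in an intron of Map3k11 (chromosome 19, 5751008 to 5751467, fold 55.7). Fold values are the authors' and are ranked only within 1 list.

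How many genes of each list held an m6A peak was counted without a test. Of the 22 pluripotency genes, 18 had a peak in WT, 16 in KO and 17 in del-cIDR, and of the 19 immediate early genes 15, 15 and 13. Of the 21 2-cell-like genes on the list that could be placed on the genome, 11 had a peak in WT, 18 in KO and 12 in del-cIDR. Ribosomal protein genes had 1, 0 and 1 of 24, replication-dependent histone genes 0 of 8 in each list, and Hox and Polycomb target genes 16, 16 and 15 of 34. The m6A machinery, which includes the writers, erasers and readers, had peaks in 18, 18 and 17 of 24 genes.

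The eCLIP peak list of ALKBH5 without its C-terminal disordered region overlapped little with that of full-length ALKBH5. The del-cIDR eCLIP list held far fewer peaks on L1 and fell in more genes overall. Each eCLIP list comes from 1 sample, so no test was possible.

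The FL list held 12458 eCLIP peaks covering 8.23 Mb and the del-cIDR list 10761 covering 4.37 Mb. L1 lay at the summit of 1960 FL peaks (15.7%) and 276 del-cIDR peaks (2.56%). Exons held 6187 and 5023 summits, introns 4455 and 4220, and intergenic sequence 1816 and 1518. Only 13.5% of FL peaks overlapped a del-cIDR peak and 16.0% of del-cIDR peaks an FL peak. For peaks in genes these shares were 13.2% and 15.7%, against 4.48% (3.95 to 5.04%) and 5.14% (4.61 to 5.85%) in 1000 random placements within the same genes. Those placements were not matched for exon or intron, so the excess can partly come from a shared preference for exons. FL peaks fell in 4325 genes and del-cIDR peaks in 5601, with 2212 genes in both. Bound cell cycle genes numbered 4 with FL and 16 with del-cIDR of 21, ribosomal protein genes 1 and 8 of 24, and replication-dependent histones 4 and 8 of 8. Glycolysis genes numbered 6 and 11 of 19 and heat shock genes 3 and 7 of 12. Fewer were bound with del-cIDR among 2-cell-like (3 and 1 of 21), primitive endoderm (3 and 1 of 13), enhancer cofactor (13 and 11 of 16), germline (3 and 2 of 20), imprinted (9 and 8 of 22) and mitochondrially encoded genes (5 and 4 of 15). These counts were not tested against the larger number of genes bound with del-cIDR.

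The strongest FL peaks without a del-cIDR partner included an L1 copy in an intron of Gng12 (chromosome 6, 66982441 to 66982887, fold 57.8) and the long coding exons of Ahnak (chromosome 19, 8984979 to 8996794, fold 57.7) and the muscle protein titin (Ttn, chromosome 2, 76607927 to 76609913, fold 56.9). The strongest del-cIDR peak without an FL partner lay in an intron of Gstm4 (chromosome 3, 107950890 to 107951181, fold 62.5). A peak in an intron of Fam19a1 (chromosome 6, 96569951 to 96570248) was the strongest FL peak found with both proteins (fold 70.8 in FL).

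FL ALKBH5 sites in genes lay on m6A peaks more often than del-cIDR sites in genes did. Of the 10642 FL eCLIP peaks in genes, 34.5% overlapped a WT m6A peak, against 9.8% (8.99 to 10.5%) in random placements within the same genes. Of the 9243 del-cIDR eCLIP peaks in genes, 14.1% did, against 5.4% (4.78 to 6.11%). The placements were not matched for exon or intron, while exons held 49.7% of FL eCLIP summits and 36.4% of WT m6A summits. The excess over them therefore does not separate binding at m6A sites from a shared preference for exons. On the KO m6A list the shares were 34.3% and 13.2%, and on the del-cIDR m6A list 32.3% and 13.2%.

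Nascent RNA differed between Alkbh5 KO and WT cells at 3342 genes. The 2-cell-like, neural, cholesterol synthesis and stress response lists were higher in the KO at a preset correlation, and these calls were lost at adjusted p = 0.181 to 0.365 with an estimated correlation. Genes on chromosomes 6 and 8 and part of chromosome 11 were higher as a block. Alkbh5 itself fell in both mutant lines.

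Alkbh5 (chromosome 11, 60427207 to 60449338) fell in the KO with a log2 ratio of -0.57 (SE 0.09, adjusted p = 0.000111) and in del-cIDR with -0.47 (SE 0.09, adjusted p = 0.0017), in each of the 4 times. In del-cIDR it stood at 0.07 (adjusted p = 0.567) when scaled to the Drosophila spike-in without the 10 min libraries. It gave 99.4 to 152 CPM (counts scaled to library size) in WT, 71.6 to 95.3 in KO and 67.4 to 107 in del-cIDR, so reads over the locus continue in the KO.

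Of 23974 genes tested by edgeR, 1758 rose and 1584 fell in the KO, 3342 in all, with 3293 moving the same way at all 4 times. DESeq2 called 3420. At least 2-fold changes were called for 217 rising and 399 falling genes. Scaled to the Drosophila spike-in, 543 rose and 159 fell. The median gene shifted by 0.29 on the log2 scale, and the share that rose went from 52.6% to 77.4%. Without the 40 min libraries 1819 genes were called, without the 60 min libraries 1782, and without the del-cIDR 10 min library, which enters the shared estimate of spread, 5095. Of the genes that rose, 1067 lay in the shifted chromosome blocks, where 37.6% of genes were called against 10.6% elsewhere. Outside the blocks 691 genes rose and 1522 fell.

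The largest rises and falls given here are among called genes with a mean count of at least 50. In the KO, Gap43 (chromosome 16, 42068805 to 42161014), an axonal growth protein, rose by 2.19 on the log2 scale (SE 0.19, adjusted p = 1.47e-07), and the eye and brain regulator Pax6 (chromosome 2, 105499245 to 105527709) by 1.92 (SE 0.17, adjusted p = 2.13e-07). Foxn4 (2.10), the extracellular matrix gene Fbn2 (1.85), the BMP target Id1 (1.82) and the lipid flippase gene Atp10a (1.73) rose as well, with adjusted p between 3.17e-06 and 1.61e-05. Zfp9 (1.64), Vax2 (1.59) and Atp2b2 (1.54), all in the shifted block of chromosome 6, were also among the 10 largest rises.

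Among the largest falls in the KO, the syntrophin gene Sntg1 (chromosome 1, 8431699 to 9370103) had a log2 ratio of -2.86 (SE 0.18, adjusted p = 2.23e-09). The oocyte genes Nlrp4a (chromosome 7, 26134538 to 26175567) and Nlrp9c (chromosome 7, 26021898 to 26103125), which lie side by side, fell with -2.84 (SE 0.16, adjusted p = 3.39e-10) and -2.50 (SE 0.14, adjusted p = 3.09e-10). Dcdc2a (-2.70), the MHC class II gene H2-Eb1 (-2.46), the adhesion receptor gene Adgrg6 (-2.39), the potassium channel gene Kcnf1 (-2.38), Aass (-2.37), Kctd16 (-2.29) and the citrate transporter gene Slc13a5 (-2.17) followed. Slc13a5 went from 42.5 to 61.8 CPM in the WT libraries to 9.49 to 14.1 in the KO libraries.

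Of the 28 fixed gene lists, 6 passed camera in the KO at a preset correlation. The 2-cell-like genes, which are active in the embryo after the first division and in rare stem cells, moved most, with 11 rising and 2 falling of 17 (median 0.68, camera adjusted p = 4.4e-07, adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone, 11 rose and 2 fell. Zscan4b rose by 1.03, Zscan4c by 0.90, Zscan4a by 0.88 and Usp17le by 1.06, while Pramel7 (-0.66) and Eif1a (-0.29) fell. Neural ectoderm genes followed, with 3 rising of 6 (median 0.56, adjusted p = 3.87e-05, adjusted p = 0.181 with an estimated correlation), both over all genes and adjusted over the list alone. They were Pax6, the neural progenitor filament gene Nes (0.95) and the neuronal tubulin gene Tubb3 (0.73, in a shifted block).

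Cholesterol synthesis genes rose in 9 of 17 cases with no fall (median 0.33, adjusted p = 9.03e-05, adjusted p = 0.365 with an estimated correlation), and 12 rose and 1 fell adjusted over the list alone. Dhcr7 (0.74), Mvd (0.73, in a shifted block), Nsdhl (0.47) and Lss (0.40) encode steps of the pathway from mevalonate to cholesterol. Amino acid and ER stress response genes rose in 9 of 17 cases with no fall (median 0.33, adjusted p = 0.000197, adjusted p = 0.333 with an estimated correlation), and in 9 adjusted over the list alone. Herpud1 (1.03, in a shifted block), Atf3 (0.74), Chac1 (0.71) and Trib3 (0.58) are targets of the ATF4 and unfolded protein responses. The p53 target genes were lower, with 5 falling of 19 (median -0.17, adjusted p = 0.0275, adjusted p = 0.365 with an estimated correlation), and 1 rising and 7 falling adjusted over the list alone. Perp (-0.99), Trp53inp1 (-0.47) and Mdm2 (-0.35) fell. The p53 call was lost without the 40 min libraries (adjusted p = 0.0562), without the 60 min libraries (0.0552) and with spike-in scaling (0.242). Mitochondrially encoded genes were lower as a list (median -0.16, adjusted p = 0.0275, adjusted p = 0.682 with an estimated correlation), with 1 of 15 falling, mt-Co2 (-0.30), both over all genes and adjusted over the list alone. That call was lost without the 10 min libraries (adjusted p = 0.0566), without the 60 min libraries (0.0512) and with spike-in scaling (0.433).

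The other 22 lists did not pass in the KO (adjusted p = 0.0573 to 0.92), though members moved in many. Without the shifted windows the pluripotency list passed as lower (adjusted p = 0.00581, and over all windows adjusted p = 0.701 with an estimated correlation). Pluripotency genes rose in 2 cases, among them Dppa3 (0.60, in a shifted block), and fell in 7 of 22, among them Tfcp2l1 (-0.60), Sox2 (-0.39) and Utf1 (-0.62), with 2 and 8 adjusted over the list alone. Primed pluripotency genes rose in 1 and fell in 3 of 9, with Dnmt3b (-1.06), Foxd3 (-0.77) and Otx2 (-0.52) falling. Immediate early genes rose in 4, with Spry4 (1.45) and Jund (1.03, in a shifted block), and fell in 1 of 18, with 7 and 1 adjusted over the list alone. Germline genes rose in 4 and fell in 3 of 19 (6 and 4 adjusted over the list alone), with the meiotic genes Mael (-1.24) and Brdt (-1.08) falling. Imprinted genes rose in 5 and fell in 5 of 21 (5 and 6 adjusted over the list alone), with Mest (1.11, in a shifted block) and the noncoding RNA H19 (-1.13). Hox and Polycomb targets rose in 3 and fell in 1 of 25 (5 and 2 adjusted over the list alone), with Hoxc8 (1.12) and Nkx2-2 (-1.34). Polycomb complex genes rose in 3 and fell in 4 of 18 (4 and 4 adjusted over the list alone), with Suz12 (-0.41) and Kdm2b (-0.56) falling and Ezh2 (0.47, in a shifted block) rising. H3K9 methylation genes rose in 2 and fell in 2 of 23 (2 and 4 adjusted over the list alone), with the germline cofactor Dnmt3l (-1.16) falling. The m6A machinery rose in 3 and fell in 2 of 24 over all genes and adjusted over the list alone, with the second m6A eraser gene Fto (0.48, in a shifted block) rising. Trophoblast genes rose in 1 and fell in 3 of 11, including Krt7 (-1.86) and Gata3 (-0.90). Every rise in the pluripotency, Polycomb complex, H3K9 methylation, m6A machinery and trophoblast lists lay in the shifted blocks, as did 3 of 5 in imprinted, 2 of 4 in immediate early and 1 of 4 in germline genes.

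Few members moved in the remaining lists of the KO comparison. Cell cycle genes rose in 3 and fell in 1 of 21, with Ccne1 (0.46) and Ccnd3 (-0.54), and 4 and 1 adjusted over the list alone. Nuclear noncoding RNA genes rose in 2 and fell in 1 of 17. Primitive endoderm genes rose in 2 of 10 (2 rising and 1 falling adjusted over the list alone) and histone demethylase genes rose in 1 and fell in 1 of 18 (2 and 3 adjusted over the list alone). Fibroblast genes fell in 2 of 6 (3 adjusted over the list alone) and interferon genes in 2 of 12, enhancer cofactors in 1 of 16 and heat shock genes in 1 of 12, and glycolysis genes rose in 1 of 20. In the shifted blocks lay 2 of the 3 rises in cell cycle genes, 1 of 2 in primitive endoderm genes and the single rises in histone demethylase and glycolysis genes. No member of the mesoderm, ribosomal protein or histone lists passed. For lists with no second count given, the count adjusted over the list alone was equal. The median and the camera direction differ in sign for primed pluripotency (median 0.07, mean -0.09, lower) and glycolysis genes, and the mean and the camera direction for primitive endoderm, germline and heat shock genes.

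With TMM scaling, nascent RNA in del-cIDR cells differed from WT at fewer genes than in the KO, with more falls than rises. The 2-cell-like genes fell together, opposite to the KO. Germline and cholesterol synthesis genes were higher as lists at a preset correlation (adjusted p = 0.352 and adjusted p = 0.361 with an estimated correlation). Genes in 5 windows of the distal X chromosome were higher together.

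By edgeR, 793 genes rose and 1043 fell in del-cIDR, 1836 in all, with 1728 moving the same way at all 4 times, and DESeq2 called 2019. At least 2-fold changes were called for 160 rising and 303 falling genes. Scaled to the spike-in, 266 rose and 125 fell (median shift 0.27), and the share that rose goes from 43.2% to 68%. Spike-in scaling without the 10 min libraries called 13472 genes, 97.4% of them higher, with a median shift of 0.49. Without the 10 min libraries 3463 genes were called, without 20 min 1014, without 40 min 588, without 60 min 667, and without the del-cIDR 10 min library 3728. Within the shifted X windows 128 genes rose and 11 fell of 338 (with the chromosome 6 window included), and outside them 665 rose and 1032 fell.

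Among the largest rises in del-cIDR were Efhc2 (X chromosome, 16998288 to 17185607), at 3.37 on the log2 scale (SE 0.31, adjusted p = 7.54e-07), and the Notch ligand gene Dll1 (chromosome 17, 15587616 to 15597134), at 2.72 (SE 0.2, adjusted p = 4.01e-08). Tex13b (2.29), Scml2 (2.10), Taf7l (1.73), Nxf3 (1.43), Arr3 (1.41) and Esx1 (1.32) all lie in the shifted X windows, and several of them are expressed mainly in the testis. Scml2 went from 12.4 to 18.7 CPM in WT to 53.4 to 70.2. The epithelial regulator Grhl2 (1.39) and Fbn2 (1.37), which also rose in the KO, complete the 10.

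Among the largest falls in del-cIDR of genes with a mean count of at least 50 was that of the 2-cell-like gene Usp17lc (chromosome 7, 103064279 to 103069087), with a log2 ratio of -2.42 (SE 0.22, adjusted p = 4.91e-07). Zfp352 and Tcstv3, with lower counts, fell further. The malic enzyme gene Me3 (-2.12), the muscle calcium channel gene Cacna1s (-2.03), Trim75 (-1.97), the hormone gene Trh (-1.92), Stk32c (-1.87), Olfr1426 (-1.85), Tmem92 (-1.85) and B3gnt6 (-1.67) followed, with adjusted p between 5.41e-06 and 0.000355.

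The 2-cell-like genes fell in 15 of 17 cases with no rise in del-cIDR (median -1.65, camera adjusted p = 2.41e-61, adjusted p = 0.00342 with an estimated correlation), and in 16 adjusted over the list alone. Zfp352 (-3.27), Tcstv3 (-2.70), Usp17lc and Gm20767 (-2.09) fell most, and all 6 Zscan4 genes fell, from -1.55 to -1.93. Germline genes rose in 6 and fell in 1 of 19 (median 0.31, adjusted p = 4.24e-05, adjusted p = 0.352 with an estimated correlation), and 9 and 3 adjusted over the list alone, with Taf7l (in the shifted block), Asz1 (1.48) and Mael (0.99) rising. Without the shifted windows the germline list had adjusted p = 0.0131. Cholesterol synthesis genes rose in 4 of 17 (median 0.22, adjusted p = 4.24e-05, adjusted p = 0.361 with an estimated correlation), and in 8 adjusted over the list alone, with Sc5d (0.57), Insig1 (0.41) and Srebf2 (0.40). Primitive endoderm genes fell in 3 of 10 (median -0.12, adjusted p = 0.0136, adjusted p = 0.352 with an estimated correlation), over all genes and adjusted over the list alone. The endocytic adaptor gene Dab2 (-1.48) and the laminin genes Lama1 (-0.59) and Lamb1 (-0.31) fell, Lamb1 changing to 0.19 with spike-in scaling without 10 min. That list stood at 0.26 in the 10 min libraries and at -0.28 to -0.23 in the others, and its call was lost without a count filter (adjusted p = 0.219) and with spike-in scaling (0.229).

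**Figure D2:**
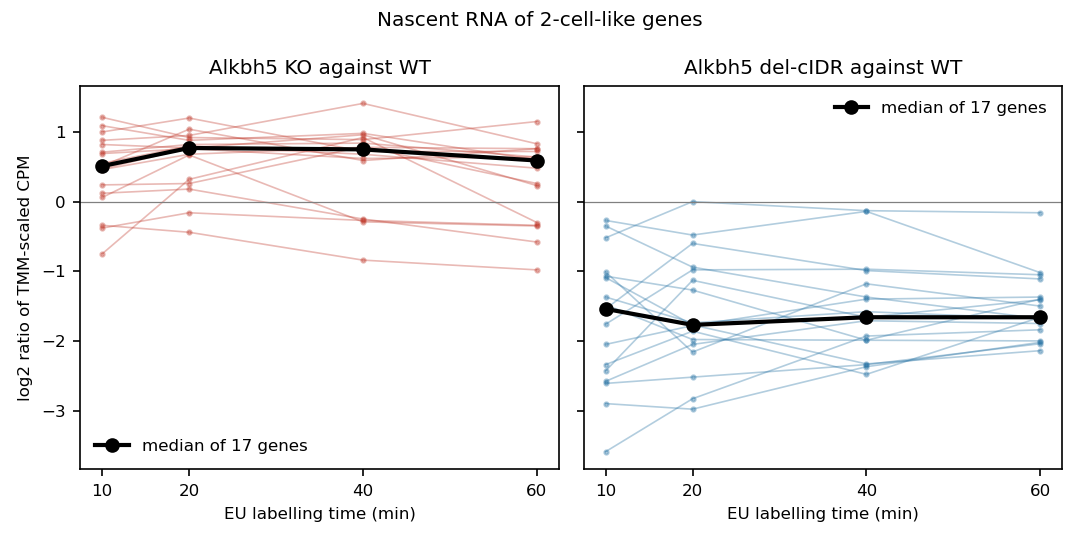
Log2 ratio of TMM-scaled CPM against WT (1 library per time and genotype) for each of 17 2-cell-like genes (thin lines) and their median (black) by labelling time in min, KO left and del-cIDR right. The medians lie above 0 at all 4 times in the KO and below -1 at all 4 times in del-cIDR.

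The other 24 lists did not pass in del-cIDR (adjusted p = 0.0501 to 0.931). Glycolysis genes came closest, with 4 rising and 1 falling of 20 (adjusted p = 0.0501, passing at 0.0333 without the shifted windows, and over all windows adjusted p = 0.785 with an estimated correlation), 7 and 1 adjusted over the list alone, and with Pgk1 (0.69) and Bnip3 (0.45) rising. Pluripotency genes rose in 3 and fell in 4 of 22, with Dppa3 (0.93) and Nr0b1 (0.65) rising and Lin28a (-0.92) falling. Imprinted genes rose in 4 and fell in 2 of 21 (5 and 2 adjusted over the list alone), with Peg3 (0.59) rising and Mest (-0.65) falling. ER stress genes rose in 3 of 17 (4 adjusted over the list alone) and nuclear noncoding RNA genes rose in 3 and fell in 2 of 17 (3 and 5 adjusted over the list alone). Trophoblast genes rose in 1 and fell in 1 of 11 (2 and 2 adjusted over the list alone), with the epithelial keratin gene Krt8 (-1.72) falling and Gata2 (1.02) rising. Immediate early genes rose in 1 and fell in 3 of 18 (2 and 4 adjusted over the list alone), with the FGF feedback gene Spry2 (-0.88) falling. H3K9 methylation genes rose in 1 and fell in 2 of 23 (1 and 5 adjusted over the list alone), with Atrx (0.45) rising. The m6A machinery rose in 1 and fell in 2 of 24 (2 and 4 adjusted over the list alone). Histone demethylases rose in 2, both in the shifted windows, and fell in 2 of 18 (3 and 3 adjusted over the list alone), and enhancer cofactors rose in 2, 1 of them in the shifted windows, and fell in 2 of 16. Neural ectoderm genes fell in 2 of 6, Tubb3 (-0.96) and Nes (-0.35, but 0.11 with spike-in scaling without 10 min).

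In the remaining del-cIDR lists at most 1 gene moved each way. Primed pluripotency, mesoderm (Wnt3, 1.59), Hox and Polycomb target (Pax2, 1.21) and ribosomal protein genes each had 1 rising member. Fibroblast (Vim, -0.47), Polycomb complex, interferon and cell cycle genes (Ccnd1, -0.64) each had 1 falling member. The p53 target, heat shock, mitochondrially encoded and histone lists had none. Adjusted over the list alone, primed pluripotency had 2 rises and 1 fall, fibroblast genes 1 and 2, interferon genes 2 falls and ribosomal protein genes 0, and the lists with no second count given were equal. The median and the camera direction differ in sign for primed pluripotency, enhancer cofactor and ribosomal protein genes, and the mean and the camera direction for trophoblast genes.

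With TMM scaling, KO and del-cIDR cells differed from each other at more genes than either differed from WT. In the same edgeR fit, 3100 genes were higher in the KO and 2776 lower, 5876 in all. Without the 40 min libraries 3601 were called, and with spike-in scaling without 10 min 9201, fewer than the 13472 of del-cIDR against WT. The 2-cell-like genes were higher in the KO by a median of 2.42 (14 of 17 called and none lower, adjusted p = 1.76e-47, adjusted p = 0.0154 with an estimated correlation), and neural ectoderm genes by 0.8 (adjusted p = 2.06e-05, adjusted p = 0.206 with an estimated correlation). Mitochondrially encoded genes (-0.31, adjusted p = 0.00177, adjusted p = 0.575 with an estimated correlation), p53 targets (-0.27, adjusted p = 0.035, adjusted p = 0.575 with an estimated correlation) and germline genes (-0.23, adjusted p = 0.0415, adjusted p = 0.655 with an estimated correlation) were lower. Among genes called against WT in both mutants, 98 rose in both (58.2 expected if independent), 156 fell in both (68.9), 226 rose in the KO and fell in del-cIDR (76.5), and 85 fell in the KO and rose in del-cIDR (52.4). Across genes, which are not independent replicates, the log2 ratios of both mutants had a correlation of 0.08 (covariance 0.016), where the shared WT libraries alone gave 0.48 (0.0317 to 0.0326) in 5 simulations. With WT libraries of different times for each mutant it was -0.07 to 0. The expected overlaps leave out the shared WT libraries, so part of any excess in the same direction can come from them. Shifts of whole chromosomes are left out as well. On chromosomes 6 and 8, 474 and 426 genes rose and 19 and 30 fell in the KO. In del-cIDR 38 and 13 rose there and 93 and 113 fell. Part of the excess in opposite directions can therefore come from these chromosomes.

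Along the chromosomes, shifts of whole chromosomes or of stretches of them stood out from scattered changes. In the KO the median log2 ratio was 0.40 over 798 genes of chromosome 6 and 0.34 over 809 genes of chromosome 8, and windows of 10 Mb on chromosome 11 between 10 and 60 Mb (268 genes) had medians of 0.34 to 0.47. Alkbh5 lies just past that stretch. A window on chromosome 14 from 10 to 20 Mb (51 genes) was lower (-0.26). In del-cIDR, 5 windows of the X chromosome between 90 and 170 Mb (187 genes) had medians of 0.30 to 0.53. These 5 windows do not fill that span. The chromosome 6 window from 130 to 140 Mb (37 genes) had -0.21. Each window given here was shifted at all 4 times. Medians of chromosomes 8 and 12 in del-cIDR were -0.13 and -0.11.

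**Figure D3:**
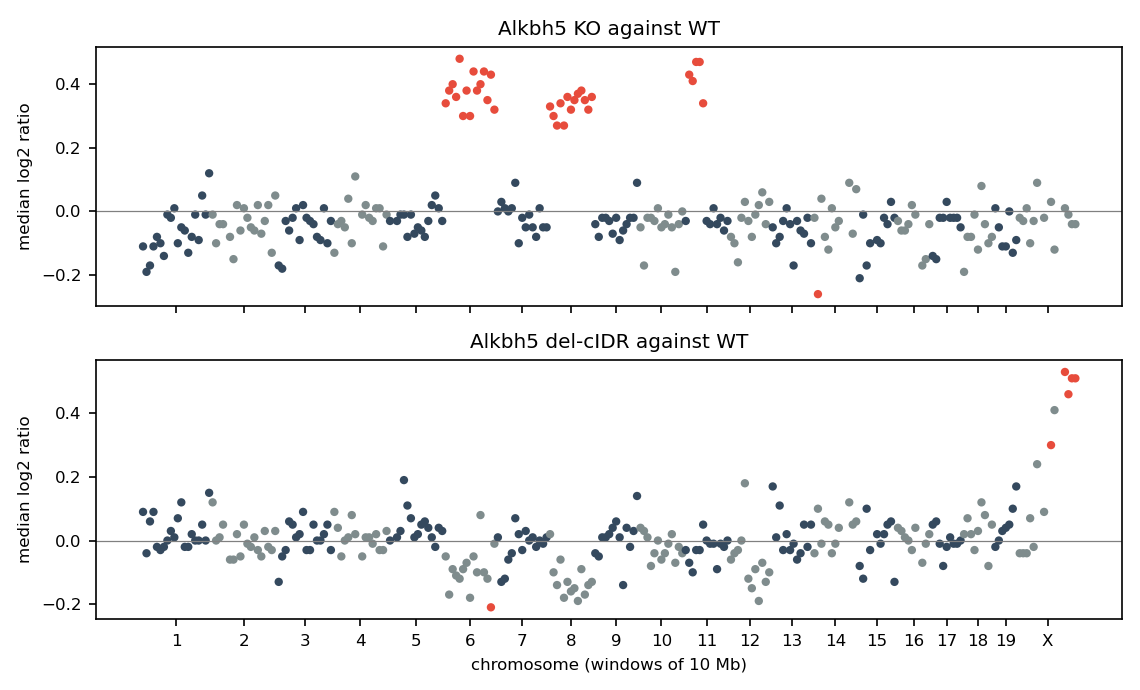
Median log2 ratio against WT of the genes in each 10 Mb window along the mouse chromosomes (points, coloured in turn by chromosome), with windows shifted by at least 0.2 at all 4 labelling times in red. In the KO the red points are the windows of chromosomes 6, 8 and part of 11 and 1 window of chromosome 14. In del-cIDR they are 5 windows of the distal X and 1 window of chromosome 6.

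The yield of nascent RNA against the spike-in rose with labelling time in all 3 genotypes. Gene reads per Drosophila read went from 475 at 10 min to 1853 at 60 min in WT, from 639 to 2411 in KO and from 299.8 to 2716 in del-cIDR. No gene had a genotype by labelling time interaction by edgeR (0 in KO with 654 at an unadjusted p under 0.05, 0 in del-cIDR with 1547), and DESeq2 called 0 and 1. Without the 10 min libraries edgeR called 0 in KO and 1 in del-cIDR (adjusted p = 0.0422). At 60 min, 112 genes were at least 2-fold higher and 139 at least 2-fold lower in the KO than in WT of 12847 with enough counts (1.95%), and 46 and 77 of 12668 in del-cIDR (0.97%). At 10 min the order was the reverse, with 53 and 105 in the KO (1.32%) and 148 and 103 in del-cIDR (2.5%).

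**Figure D4:**
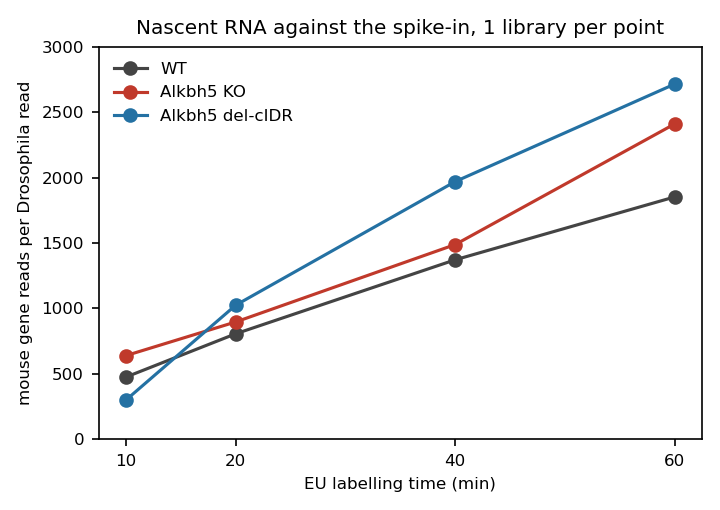
Mouse gene reads per Drosophila spike-in read (points, 1 library each) by labelling time in min in WT, KO and del-cIDR cells. At 60 min the values are 1853, 2411 and 2716.

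Repeat families as a whole were not called in nascent RNA, while long copies of some retroviral families changed. Of 60 families edgeR called 0 in KO and 0 in del-cIDR (2 and 2 at an unadjusted p under 0.05), and DESeq2 0 and 0. Without the 10 min libraries 1 family was called in KO, and without the del-cIDR 10 min library 3. L1 had log2 ratios of -0.02 in KO (SE 0.06, adjusted p = 0.973) and -0.03 in del-cIDR (adjusted p = 0.965), which become 0.26 and 0.23 with spike-in scaling. These counts leave out reads with several placements, so near-identical L1 copies weigh little in them.

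Divided by place and length of the copies, intergenic ERVK and ERV1 copies of 5 kb or longer fell in the KO, with -0.42 (adjusted p = 0.00438) and -0.36 (adjusted p = 0.00438), 2 of 5 classes called of 119. The others were ERV1 intergenic copies under 5 kb (-0.29), ERV1 copies of 5 kb or longer in genes (-0.26) and unclassified intergenic repeats (-0.40). In del-cIDR 1 class fell, intergenic satellites of 5 kb or longer (-1.07, adjusted p = 0.000292). Without the 40 min or the 60 min libraries 0 classes were called in KO and without 20 min 3, and without 10 min 12 in KO and 11 in del-cIDR. With spike-in scaling 0 were called in either. Intergenic ERVL copies of 5 kb or longer, the class that holds the retrovirus of 2-cell embryos, had -0.64 in del-cIDR (adjusted p = 0.174), and -1.03 (adjusted p = 1.54e-17) without the del-cIDR 10 min library.

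Single copies of 5 kb or longer (10757 tested) rose in 39 cases and fell in 119 in the KO, and 240 were called in del-cIDR, 36 of them rising. In del-cIDR, 113 of 605 ERVL copies fell and 1 rose, with 471 falling without 10 min, 32 without 20 min, 13 without 40 min and 7 without 60 min. Of 9518 L1 copies, 34 rose and 79 fell in the KO, and 18 rose and 85 fell in del-cIDR. Among called intergenic copies of this length, the largest falls in the KO lay next to Nlrp4a. They were an ERVK copy (chromosome 7, 26190680 to 26195679, -3.98, SE 0.45, adjusted p = 1.13e-07) and an L1 copy (chromosome 7, 26182605 to 26188527, -3.52, adjusted p = 1.46e-06). In del-cIDR an ERVK copy on chromosome 7 (62214399 to 62222074) rose by 2.65 (adjusted p = 3.52e-06), and an L1 copy on chromosome 13 (80445733 to 80452035) fell with -3.13 (adjusted p = 6.98e-06). Length was restricted after copies of every length had been tested, where 1890 rose and 3835 fell in the KO and 650 rose and 2014 fell in del-cIDR of 320289.

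For a change shared by the 4 histone demethylases on loss of the disordered region, edgeR called 0 repeat families in chromatin-associated RNA (8 at an unadjusted p under 0.05) and DESeq2 called 5. KDM4A and KDM4B libraries had lower L1 and retroviral RNA without it, though by little or nothing in copies under 5 kb within genes, and in KDM4A intergenic copies of other families were as low. In KDM6A and KDM6B libraries the sign of the whole L1 family, and in KDM6B that of the ERVK family, depends on the scaling. ERV1 in KDM6B was above 0 with each scaling (0.11 to 0.34). With TMM scaling, intergenic copies of 5 kb or longer were higher in KDM6B for L1 (0.66) and ERVK (0.46). The difference between the pairs did not pass correction.

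Of the 60 families tested, edgeR called 1 when scaled to library totals. L1 had a shared log2 ratio of -0.10 (adjusted p = 0.423). Per protein, in the order KDM4A, KDM4B, KDM6A and KDM6B, L1 had -0.28, -0.21, 0.00 and 0.08, ERVK -0.26, -0.21, 0.03 and 0.09, and ERV1 -0.23, -0.19, 0.04 and 0.26, with KDM6B at -0.06 for both L1 and ERVK when scaled to library totals. The KDM6 pair exceeded the KDM4 pair by 0.29 for L1 and 0.29 for ERVK (adjusted p = 0.259 each). Divided by place, L1 copies under 5 kb had -0.66 in KDM4A and -0.37 in KDM4B between genes but 0.02 and -0.04 within genes. L1 copies of 5 kb or longer had -0.45, -0.32, 0.04 and 0.66 between genes in the order above. Within genes they had -0.17, -0.22, 0.02 and 0.43. In KDM4A, intergenic copies of L2 (-0.65), CR1 (-0.70) and Tigger (-0.67) were as low as those of L1. rRNA fragments had 1.55, 0.94, -0.25 and 0.44. The families with the smallest unadjusted p in the shared test were MULE-MuDR (-0.35) and hAT-Tip100 (0.53), both annotated as DNA transposons, with adjusted p = 0.259. Of the 17310872 hAT-Tip100 reads, 17067855 lay in intergenic copies. Divided by place, those copies had 0.58 and the copies in genes -0.02, so the value does not describe the family as a whole. Of 12058 single copies of 5 kb or longer edgeR called 0 (689 at an unadjusted p under 0.05), and over copies of every length 1 of 522196. ERVL copies of 5 kb or longer had a median of -0.32, with 164 of 613 at an unadjusted p under 0.05. This fall lay in the KDM4 proteins. Summed between genes these copies had -0.76 in KDM4A, -0.68 in KDM4B, 0.02 in KDM6A and 0.07 in KDM6B.

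**Figure D5:**
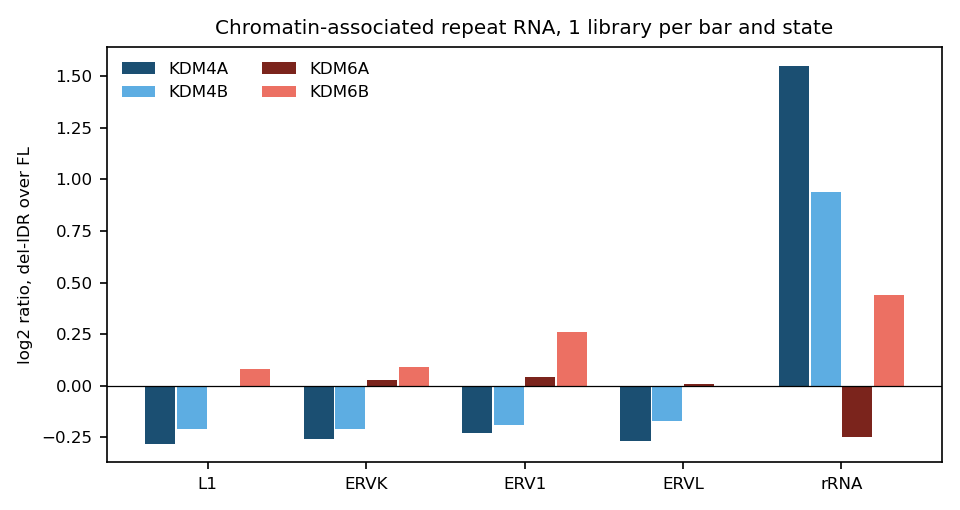
Log2 ratio of del-IDR over FL in chromatin-associated RNA for 5 repeat families and 4 proteins (bars, 1 library per state), scaled by TMM over repeats. KDM4A and KDM4B lie below 0 for L1 (-0.28 and -0.21) and above 0 for rRNA (1.55 and 0.94), and the KDM6B bar for L1 (0.08) becomes -0.06 when scaled to library totals.

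In Arabidopsis seedlings the Col-0 list held 1619 regions covering 508.8 kb, with a median width of 242 bp. Of these, 34 lay on the mitochondrial and 25 on the plastid genome. The control RNA carrying m6A was among the regions of all 5 lists.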

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

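All tests of the 2-cell-like genes and all counts of other splits given here were chosen after the results had been seen.

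The 2-cell-like genes were the list in which both mutants differed most from each other, with a median difference of 2.42 between KO and del-cIDR. An exchange of WT with KO libraries is argued against, since Alkbh5 was lower in the KO (upper 95% limit -0.40, and below 0 with spike-in scaling too), and so is a shift of reads among near-identical Zscan4 copies, since the summed Zscan4 count fell in del-cIDR at every time, least at 10 min (-1.42), and was higher in the KO at every time (0.65 to 0.90). A different share of 2-cell-like cells in the cultures is a candidate explanation. ERVL copies of 5 kb or longer, which hold the retrovirus of that state, had a median of -0.72 in del-cIDR. It was 0.21 at 10 min and -0.87 to -1.05 at the later times. In the KO the median was 0.24, with -0.05 at 10 min and 0.25 to 0.41 later, and 1 of 605 copies was called. Chance cannot be excluded for the number of these copies called in del-cIDR. A difference between cultures or clones that has nothing to do with Alkbh5 cannot be told apart from an effect of the mutations, which remains open and untested, since there is 1 replicate number per genotype and time, and neither can an exchange of WT with del-cIDR libraries, since Alkbh5 was lower in del-cIDR with TMM (upper limit -0.30) but stood at 0.07 with spike-in scaling without 10 min. As many calls on this list came from 1 of 35 splits of the libraries in KO (13 genes called, highest other split 0) and in del-cIDR (15 called, highest other 0), but most splits mix the labelling times, and the 8 that keep 1 library of each time in both groups (highest other 0 in each) are too few for a share under 0.05.

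Mitochondrially encoded genes differed between KO and del-cIDR by a median of -0.31 in the test of the difference (camera adjusted p = 0.00177 at a preset correlation, adjusted p = 0.575 with an estimated correlation). In the KDM libraries, ERVK (KDM6 minus KDM4 0.29), ERV1 (0.36) and B4 (-0.06) lay on one side of 0 in both KDM4 proteins and on the other side in both KDM6 proteins with TMM scaling, B4 only just (0 in KDM6A when rounded). With library totals ERVK and B4 no longer did, and ERV1 did with every scaling. Only 10 of the 60 families were examined for this, and the differences did not pass correction (adjusted p = 0.259, 0.259 and 0.527).

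Single libraries stood apart from the other 3 of their group in 14 of 98 groups of 4 that were examined, where chance gives about 1 in 20 groups, or 4.9 here. The del-cIDR 10 min library, the shallowest, accounts for 9 of them. In it the 10 most abundant genes took 4.87% of reads (3.46 to 3.7% in the others), and the list medians were 0.06 for pluripotency (others -0.12 to -0.09), 0.26 for primitive endoderm (-0.28 to -0.23), -0.31 for the m6A machinery (0.01 to 0.04) and 0.24 for heat shock genes (-0.15 to -0.11). The same library had -0.33 for MaLR, -0.37 for B1, -0.32 for B2 and -0.34 for B4 repeats, where the others lay between 0.02 and 0.12. In the KO 10 min library 32304 genes were detected (others 32882 to 32977), ribosomal protein genes had a median of 0.11 (others -0.15 to -0.11), and rRNA repeats had -0.29 (others -0.05 to 0). In the KO 20 min library the p53 target median was -0.14 (others -0.2 to -0.19) and B2 repeats had 0.09 (others -0.06 to -0.05).

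The Col-0 list of Arabidopsis, outside any comparison, held 2 regions on the unmodified control RNA and 4 on ERCC control sequences, where the other 4 lists held 0.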

How the results depend on the processing

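Spike-in scaling, leaving out the del-cIDR 10 min library and the calls outside shifted windows were chosen after the results had been seen, while the other settings given here were planned. No paired analysis was possible because the replicate number, the same for all samples, pairs none, so labelling time and protein served as the blocks of the fits. Where a value changed, the cause was not tested.

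The order of the L1 shares (KO over WT over del-cIDR for m6A, FL over del-cIDR for eCLIP) held at -log10 q of at least 5, at a fold of at least 4 and, for WT and KO, with the same number of peaks per list. At -log10 q of at least 5 they were 34.1% in WT, 48.1% in KO, 24.3% in del-cIDR and 15.0% in FL eCLIP, and at a fold of at least 4 40.4%, 54.1%, 27.6% and 21.1%, with 6.18% in del-cIDR eCLIP. With the same number of peaks per list WT had 29.0% and KO 37.1%. The del-cIDR list, the shortest, kept its 25.8%. The gap between WT and del-cIDR was thus much smaller than in the full lists, where WT had 38.0%. WT peaks overlapped by KO went to 82.3% at a fold of at least 4, 79.9% with the same number per list, 81.2% with at least 50% of the peak and 69.6% with summits within 100 bp. WT peaks overlapped by del-cIDR went to 66.5% at the stricter q, 62.1% at a fold of at least 4, 79.7% with the same number, 57.9% with at least 50% and 56.1% by summits. FL eCLIP peaks overlapped by del-cIDR went to 12.1% at the stricter q, 5.94% at a fold of at least 4, 11% with at least 50% and 9.7% by summits. Counting only overlaps of at least 50%, eCLIP peaks in genes on WT m6A went to 19.3% for FL and 6.93% for del-cIDR.

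Leaving out each time gave 1782 to 4138 called genes in KO, 588 to 3463 in del-cIDR and 3601 to 7348 for KO against del-cIDR. Without a block for time 1423, 576 and 3327 were called. Spike-in scaling gave 702, 391 and 1329, and without 10 min 5382, 13472 and 9201. Without the del-cIDR 10 min library 5095 genes were called in KO and 3728 in del-cIDR. Outside the shifted windows 2213 were called in KO. Nascent repeat families called in KO ranged from 0 to 1 when a time was left out, and were 1 with TMM within the repeat table and 3 without the del-cIDR 10 min library. The KDM families called were 1 with library totals and 5 by DESeq2. The del-cIDR interaction gave 1 gene without 10 min and 1 by DESeq2. Genes at least 2-fold apart at 60 min were 4.26% and 3.41% at 50 counts and 0.67% and 0.18% at 1000 counts in KO and del-cIDR.

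Some named genes reversed with spike-in scaling. In del-cIDR without 10 min these were Alkbh5 (0.07), Nr5a2 (0.24), Lamb1 (0.19), Nes (0.11), Fn1 (0.21), Igf2bp1 (0.04), Rbmx (0.31), Kdm3a (0.16), Kdm2b (0.13), Cbx5 (0.16), Atf7ip (0.27), Crebbp (0.16), Ctcf (0.20), Mcm2 (0.24) and Rpl13a (0.40), and in KO with all times Fn1 (0.01) and Atrx (0.04). This scaling raises every gene of a library by 1 factor, so small falls cross 0. Over the genes named from lists or by rank and their settings, 2866 values kept direction and side of the threshold, 314 lost the call, 128 gained one and 17 reversed. For gene lists 531 kept it, 8 lost it and 21 gained it, and for repeat families 250 kept it and 2 gained it.

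Merging adjacent peaks and the count filter for repeat families changed nothing. Other settings for genes in the KDM cells, m6A enrichment, plant scores and other units had been planned and were not run. The 3918731 reads of the del-cIDR 10 min library limit what can be called for weak genes at that time.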

Other observations

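The tests of genes without peaks and of intergenic copies in the shifted chromosome blocks, of L1 transcription, and the counts of other splits were chosen after the results had been seen, while the tests by expression and length of genes, by strength of m6A peaks and of nascent RNA at genes with changed peaks were written before theirs were.

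A stretch of chromosome 7 near 26 Mb lost nascent RNA in the KO across neighbouring features. Nlrp9c and Nlrp4a fell with -2.50 and -2.84, an L1 copy and an ERVK copy just downstream with -3.52 and -3.98, and Cyp2b23, the next gene tested, with -2.04 (adjusted p = 0.000176). In del-cIDR, Nlrp9c (-0.98) and Nlrp4a (-0.73) fell too. This region was singled out after its values were seen.

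In the KO, genes of chromosomes 6 and 8 and part of chromosome 11 were shifted up together, and in del-cIDR those of 5 windows of the distal X. An effect limited to genes with called m6A or eCLIP peaks is argued against, since genes of these blocks with no such peak were shifted as much (median 0.38 in KO, 0.50 in del-cIDR). A gene without a called peak may still be bound or methylated, and an effect through RNA of neighbouring loci was not tested. A difference in copy number between the cell lines is a candidate explanation, since the lowest median among 3 equal groups of genes by count or by length was still 0.36 in KO and 0.37 in del-cIDR, and intergenic repeat copies in the blocks exceeded those elsewhere by 0.30 and 0.23. No DNA library was used, so this was not tested on DNA.

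L1 copies gained m6A peaks in the KO list and lost them in the del-cIDR list. Depth or threshold of the peak calls alone is argued against: within 5 equal groups of WT peaks by strength, the share found again in del-cIDR was lower for L1 than for exon peaks by a mean of -19.7 points, though the mean over groups was weighted by L1 peaks when the test was written, and the 2 strongest groups showed almost no gap (-2.5 and -0.1 points) because nearly all their peaks were found. In KO the same mean was 18.3 points in favour of L1. List length mattered as well. With the same number of peaks per list, 79.7% of WT peaks overlapped a del-cIDR peak and 79.9% a KO peak. In the full lists these shares were 63.7% and 84.0%, so a part played by depth or threshold stays open. A fall of L1 transcription by 0.3 in del-cIDR, the size that was required, is argued against under TMM, for uniquely placed reads only. Nascent RNA of intergenic L1 copies of 5 kb or longer had 0.01 (SE 0.1) there, with a lower 95% limit of -0.19. Reads with several placements were left out, so near-identical L1 copies lose reads and the ratio does not show what they do. Without the del-cIDR 10 min library the ratio was -0.13 (SE 0.05), so a smaller fall is not excluded. Spike-in scaling gave 0.22 in del-cIDR, with an SE of 0.28 that is too wide to decide. A rise in the KO cannot be told apart, since the ratio was 0 with an upper limit of 0.20 under TMM but 0.27 (SE 0.28) with spike-in scaling. An effect of ALKBH5 activity or targeting stays open as the explanation that the design names.

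Whether genes with changed peaks changed in nascent RNA was tested outside the shifted blocks against 10000 lists matched on expression. The 1572 genes that gained m6A peaks in the KO differed by 0.02, above 99.85% of the matched lists, with 131 rising and 182 falling. The 2998 genes that lost m6A peaks in del-cIDR differed by 0, and the 2591 genes with eCLIP peaks only in del-cIDR by 0. None of the 3 medians reached the bound of 0.1 that had been set for a change.

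Over all splits of the same libraries, counted once each, only the real one (1 of 35) gave as many calls for the genes in KO (3342, highest other split 0), in del-cIDR (1836, highest other 1) and between the mutants (5876, highest other 0), for repeat classes by place and length in KO (5, highest other 3) and for long copies in KO (158, highest other 35) and del-cIDR (240, highest other 162). Most of these splits mix the labelling times. Only 8 keep 1 library of each time in both groups, too few for a share under 0.05, and among these the highest other was 0 for genes in KO, 1 in del-cIDR and 0 between the mutants, 1 for repeat classes in KO, 0 for long copies in KO and 162 for long copies in del-cIDR. Chance cannot be excluded for the repeat classes in del-cIDR (1 called, highest other 3, 5 of 35) or for long ERVL copies in del-cIDR (114 called, highest other 126, 2 of 35), where the split that exchanges the 10 min WT and del-cIDR libraries gave more. With 0 calls every split is as high by construction, so the share says nothing about chance. This holds for the interaction (0 called, highest other 2067 in KO and 961 in del-cIDR, 35 of 35 each), where the highest split in both puts the 10 and 20 min libraries of 1 genotype with the 40 and 60 min libraries of the other, so the libraries are structured by time. It also holds for nascent repeat families (0 called, highest other 1 in KO and 0 in del-cIDR, 35 of 35 each), and in the KDM cells for families (0 called, highest other 5, 32 of 32) and long copies (0 called, highest other 174, 32 of 32), where the highest splits are those that rest the contrast on KDM4A and KDM4B.

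Of the 1619 Col-0 regions of Arabidopsis, 52.1% overlapped the list coded 5L2, 79.0% 5L2mut, 76.5% 5W and 76.9% 5Wmut, and 51.4% all 4. These lists held 1470, 4530, 2835 and 3241 regions, and the labels do not say which line each code stands for.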
